A study of Mus musculus with 2 samples.

How the data were processed

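Gene expression was measured by droplet-based single-cell RNA sequencing in 2 libraries of mouse lung, 1 per group. The deposited matrices hold raw counts, that is UMI counts as whole numbers per gene and barcode, and the authors applied no scaling to them. Each library has its matrix a second time with the same entries, so 1 of each was read. Reads had been aligned to mm10 with Cell Ranger, whose version is 7.1.0 per the file headers and 7.10 per the labels. Barcodes had been called as cells by that tool. The annotation, the chemistry and the number and sex of the mice behind each library are not given in the sources used here. The protocol text read here stops partway through the mixing of the sorted lineages, so later steps such as pooling and loading are not known. The sample labels name epithelial and CD45+ cells, whereas the protocol also sorts endothelial and mesenchymal cells. The files list 32285 genes.

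The PBS library held 10053 barcodes with 81233499 UMIs, at medians of 5756 UMIs, 2020 genes and 5.16% mitochondrial UMIs. The Pam2ODN library held 10764 barcodes with 92844446 UMIs, at medians of 6187.5 UMIs, 2192 genes and 5.47% mitochondrial UMIs. Barcodes with fewer than 200 genes (42 and 67) or more than 15% mitochondrial UMIs (1932 and 2233) were left out, which kept 8079 and 8464. Doublets were called per library with Scrublet at its own threshold. It has not worked in the PBS library, where it set the threshold at 0.706 and called 1 barcode (0.0124%), against a threshold of 0.323 and 187 calls (2.21%) in the Pam2ODN library. Doublets therefore remain in the PBS library, and some can remain in the Pam2ODN library too. Unnamed cluster 28, with both B cell and T cell genes among its top 10, held 48 and 35 barcodes. The cells kept were 8078 and 8277, with 75798583 and 82661963 UMIs and medians of 2370 and 2651 genes. The ribosomal RNA-like gene Gm42418 took 6.32% and 7.88% of the UMIs.

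Both libraries were clustered together without integration, on log-normalised counts of 2000 variable genes (mitochondrial genes, Gm42418, AY036118 and Xist left out), 30 principal components, 15 neighbours and the Leiden method at resolution 1. Clusters were named by cell type markers that were fixed before the data were examined. The naming rule was set after the clusters were seen. It takes the type with the highest mean log2 ratio of its markers over the median of the clusters (10 CPM added), at a score of at least 2 and a lead of 1.1 over types of another lineage, with at least 3 markers of 3 or more UMIs. In a cluster of low UMI counts at least 1 of its top 10 genes had to be a marker, and fewer than 2 of them markers of another lineage. This kept the Scgb1a1-led cluster of 568 and 171 barcodes unnamed, whose top genes include 3 haemoglobin genes. T, natural killer and innate lymphoid clusters, dendritic clusters and 1 mixed mesothelial and secretory cluster were clustered again and named at a score of 1.5 (0.4 for CD8 T cells). Classes are called "like" because they rest on transcripts alone. Cluster 5 and others held cells mostly of 1 library, and a cluster of that kind can be the library itself.

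Shares of immune classes were taken of the immune cells, and of epithelial classes of the epithelial cells, since a sort set the split between compartments. Shares have exact Clopper-Pearson 95% intervals. Intervals of folds between shares are normal approximations on the log scale. For expression, UMIs were summed per library and class and scaled to the class total (CPM), and the ratio Pam2ODN over PBS was taken. CPM have exact Poisson intervals and ratios exact conditional binomial intervals. With 1 library per group no test across samples was possible, and cells are not replicates, so all intervals cover counting error only. Classes with at least 200 cells in each library were compared. Classes with 50 or more in each were read for list members alone, and smaller ones for shares alone.

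Named genes followed a rule fixed before the data were examined. A gene needed at least 50 CPM and 30 UMIs in the library where it was higher, an interval that excludes equality, and at least 10% of the CPM of the class with the most, which guards against free RNA. The genes with the largest ratios were then taken, 10 in each direction in 2 epithelial and 3 immune classes, and 5 in each direction in the other 3 classes compared, and not every one of them is reported. A count of 0 was set to 3 UMIs. Sex-linked, immunoglobulin variable, haemoglobin and mitochondrial genes and unnamed gene models were left out. Marco, which the rule also named in alveolar-macrophage-like cells, is a marker by which that class was named and is not reported. In addition, members of 29 gene lists fixed beforehand were named where they lead their list or differ at least 2-fold. Of 566 list symbols, 9 were not in the files. Genes that share a symbol (38 symbols) were kept apart. Gene positions came from GENCODE M21, in which all 530 gene identifiers looked up were found.

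For each list the median log2 ratio was taken over members with at least 20 UMIs in the class. Not every list is reported for every class, and no rule for that choice is stated. Its interval came from 400 Poisson draws of the counts, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. Shares of cells with a UMI of a gene were taken unthinned and after thinning each cell to 1000 UMIs (shallower cells left out), beside B-cell-like cells as background.

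The computation of the ratios was checked on simulated data. Summed UMIs of the AT2-like class were drawn anew as Poisson counts with 200 genes altered 1.5-, 2-, 4- or 8-fold, 50 each. These draws follow the model that the intervals assume and leave out an uneven spread of UMIs over cells. They therefore do not show how the intervals hold for real cells. Intervals held the true fold in 95.6% of 14722 unaltered genes and in 96%, 94%, 100% and 94% of the altered ones. They excluded equality in 4.44% of the unaltered genes and in 92%, 100%, 100% and 100% of the altered ones.

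Alternatives chosen before the data were examined were no filter on cells, at least 500 genes with at most 5% mitochondrial UMIs, doublets kept, the 8% of barcodes with the highest Scrublet scores left out, resolutions 0.5 and 2, response genes left out of the clustering, and thinning to 2000 UMIs before clustering. For expression they were edgeR's TMM factors, median-of-ratios factors, totals without mitochondrial and ribosomal protein genes, each cell counted alike, other UMI minimums (1 or 100 per list member, 10 for named genes), members past the free RNA guard alone, no guard, and thinning to 500 UMIs. Chosen after seeing the data were Xist-only cells, Y-only cells, cells of at least 1000 UMIs, the top cell of each gene left out, totals without Gm42418 and AY036118, the top 8% of Scrublet scores for list medians, and marker genes left out of the clustering.

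The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 (its Scrublet), anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. TMM and median-of-ratios factors were computed in Python by their published formulas. Clusters without a name were left out of the comparisons, as were read-level data, which are not used here.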

Results

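Single-cell RNA sequencing was done on dissociated lungs of naïve BALB/c mice, 12 h after 100 µg of house dust mite extract (HDM) was given into the trachea. The mice had breathed 1 aerosol for about 40 min, 7 days before HDM. The aerosol was phosphate-buffered saline (PBS) or Pam2ODN, a mix of Pam2CSK4 at 4 µM, a lipopeptide that activates the Toll-like receptor pair TLR2 and TLR6, and a CpG-type oligodeoxynucleotide (ODN) at 1 µM, which activates TLR9. The comparison asks how cells of lungs exposed to the agonists a week earlier differed, in the first hours after the allergen, from cells of lungs exposed to PBS alone. There was 1 library per group, called here the PBS library and the Pam2ODN library. No difference below was checked against replicates, so no test across samples was possible and every interval covers counting error only.

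The PBS library held 81233499 UMIs (unique molecular identifiers, each a counted transcript) in 10053 barcodes. The Pam2ODN library held 92844446 UMIs in 10764 barcodes. After filtering, 8078 and 8277 cells were kept, with medians of 6982 and 7922 UMIs. Cells had been sorted into immune (CD45+), endothelial (ICAM2+), epithelial (E-cadherin+) and remaining mesenchymal cells and mixed again, so the split between these compartments was set by the sort. Immune-like cells made up 48.9% of the PBS library and 39.7% of the Pam2ODN library, epithelial-like cells 17.2% and 19.3%, endothelial-like cells 13.9% and 21.2%, and mesenchymal-like cells 9.74% and 15.4%. Shares below are therefore given within the immune or the epithelial compartment. Clusters left without a name held 9.85% of the PBS cells and 4.02% of the Pam2ODN cells. The largest of these, led by the secretory gene Scgb1a1, held 7.03% and 2.07%.

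Alveolar-macrophage-like cells, the resident phagocytes of the airspace, took up a larger part of the immune cells in the Pam2ODN library. They numbered 225 of 3949 immune cells after PBS (5.7%, exact Clopper-Pearson 95% interval 5 to 6.47) and 582 of 3284 after Pam2ODN (17.7%, 16.4 to 19.1), which is 3.11-fold (2.69 to 3.6). T-cell-like cells were 27.5% and 20.4% (0.741-fold, 0.681 to 0.806), and natural-killer-like cells 3.9% and 2.53% (0.648-fold, 0.498 to 0.843). B-cell-like cells were 30.2% and 28%. Neutrophil-like cells, the early responders to inhaled irritants, were 16.3% and 14.5%. Immune shares add up to the whole, so the larger alveolar-macrophage-like share by itself lowers those of the other classes. How much of their lower shares this makes up was not computed. Group 2 innate lymphoid-like cells (ILC2), a source of type 2 cytokines, were 14 and 12 cells, or 0.355% (0.194 to 0.594) and 0.365% (0.189 to 0.637), so no difference in them was detectable at this depth.

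The other myeloid classes depended on how the cells were clustered. Classical-monocyte-like cells, which enter inflamed tissue from the blood, were 9.07% and 5.18% of immune cells (0.571-fold, 0.479 to 0.681), but 0.952-fold when the marker genes were left out of the clustering. Interstitial-macrophage-like cells were 1.29% and 3.23% (2.5-fold, 1.8 to 3.48), but 1.06-fold without the marker genes. The alveolar-macrophage-like fold was 3.41 without them. Dendritic-like cells, which carry allergen to lymph nodes, were 1.95% and 3.38% (1.73-fold), but 0.761-fold when cells were thinned to 2000 UMIs before clustering. Most of them lay in sub-cluster D0, led by monocyte genes such as F13a1 (46 and 32 cells), and in D2, led by Mgl2 and macrophage genes such as C1qa (6 and 45), so the kinds of cell in this class differed between the libraries. Among epithelial cells, alveolar-type-2-like (AT2-like) cells, the surfactant producers, were 76.3% and 81.9%, and alveolar-type-1-like (AT1-like) cells, the thin gas-exchange cells, 19.1% and 14.3% (0.745-fold, 0.634 to 0.876). The AT1-like fold was 1.96 in cells of at least 500 genes and at most 5% mitochondrial UMIs, so its direction was not settled. AT1-like cells had median depths of 841.5 and 1263.5 UMIs. All epithelial shares leave out the unnamed Scgb1a1-led cluster (568 and 171 barcodes), which scored highest for secretory cells (4.56). Counted as epithelial, it would lower these shares more in the PBS library. Shares with it were not computed.

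**Figure D1:**
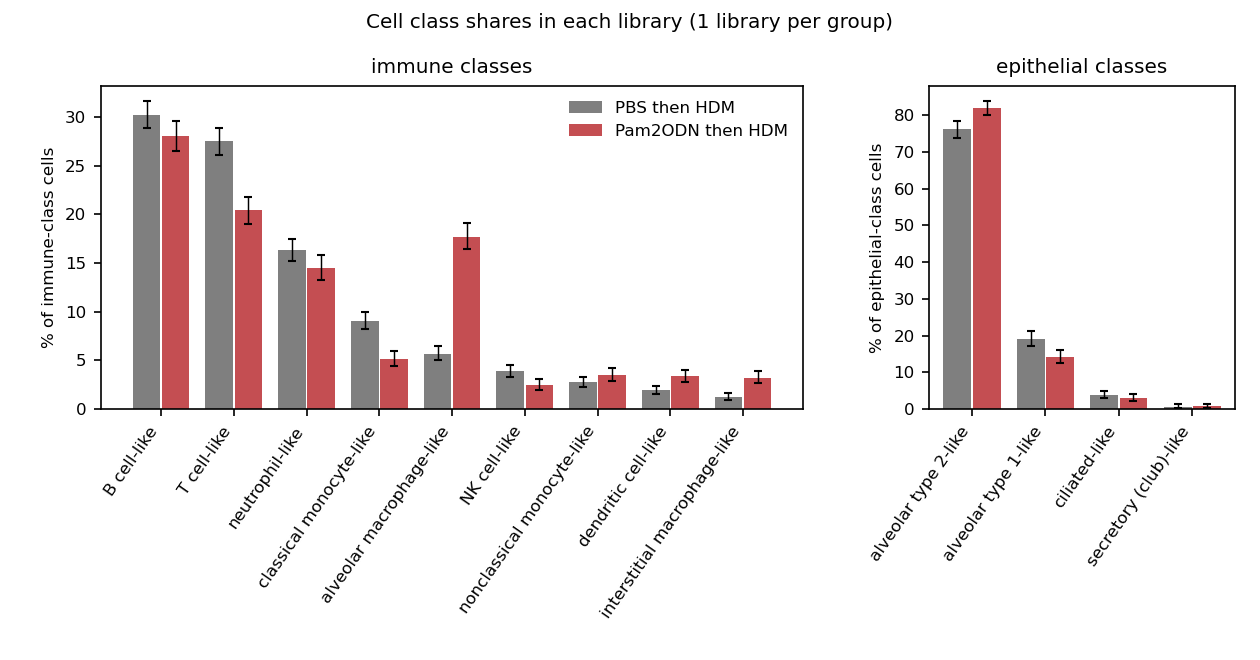
Percent of immune-class cells (left) and of epithelial-class cells (right) in each named class of the PBS (grey) and Pam2ODN (red) library, 1 library per group, immune classes of at least 50 cells in 1 library; bars are shares and error bars exact 95% binomial intervals of counting error. Alveolar-macrophage-like cells stand at 5.7% and 17.7% and T-cell-like cells at 27.5% and 20.4%.

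AT2-like cells of the Pam2ODN library had lower levels of the genes with which epithelium calls in other cells. Ccl20, a chemokine that attracts dendritic and lymphoid cells, stood at 53.8 CPM (UMIs summed over the cells and scaled to the class total) after PBS and 1.05 after Pam2ODN, a log2 ratio of -5.68 (-6.30 to -5.12). The neutrophil chemokines Cxcl5 (184 and 17.1 CPM, -3.42, -3.57 to -3.28) and Cxcl1 (389 and 56.6 CPM, -2.78, -2.86 to -2.70) were lower too. Csf2, which encodes the growth factor GM-CSF that primes dendritic cells for allergen, stood at 90.4 and 14 CPM (-2.69, -2.86 to -2.52). Retnla, a gene of type 2 responses, stood at 1234 and 81.5 CPM (-3.92, -3.99 to -3.86). These values sum over 1060 and 1310 cells with 21776758 and 24754376 UMIs. Ccl20 in the Pam2ODN library was 26 UMIs, of which 69.2% lay in 1 cell.

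The other 5 of the 10 genes with the largest lower values were Il4i1, an amino acid oxidase (-3.82), Tnip3, an inhibitor of NF-kB signalling (-3.36), the co-stimulatory receptor gene Tnfrsf9 (-2.61), Sdf2l1, of the endoplasmic reticulum (-2.24), and Noxo1, an organizer of the superoxide-producing NADPH oxidase NOX1 (-2.08). The 10 genes with the largest higher values differed less, from 1.03 to 1.35. They were Dpyd, of pyrimidine breakdown (1.35, 1.20 to 1.51), the copper transporter gene Atp7b (1.20), Abca17 (1.16), the lipoprotein receptor gene Vldlr (1.15), the aldehyde oxidase gene Aox3 (1.14), Mitf, a transcription factor (1.11), Plekhg5 (1.08), Rapgef5 (1.07), Sh3rf3 (1.06), and Gpam, which starts glycerolipid synthesis (1.03).

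**Figure D2:**
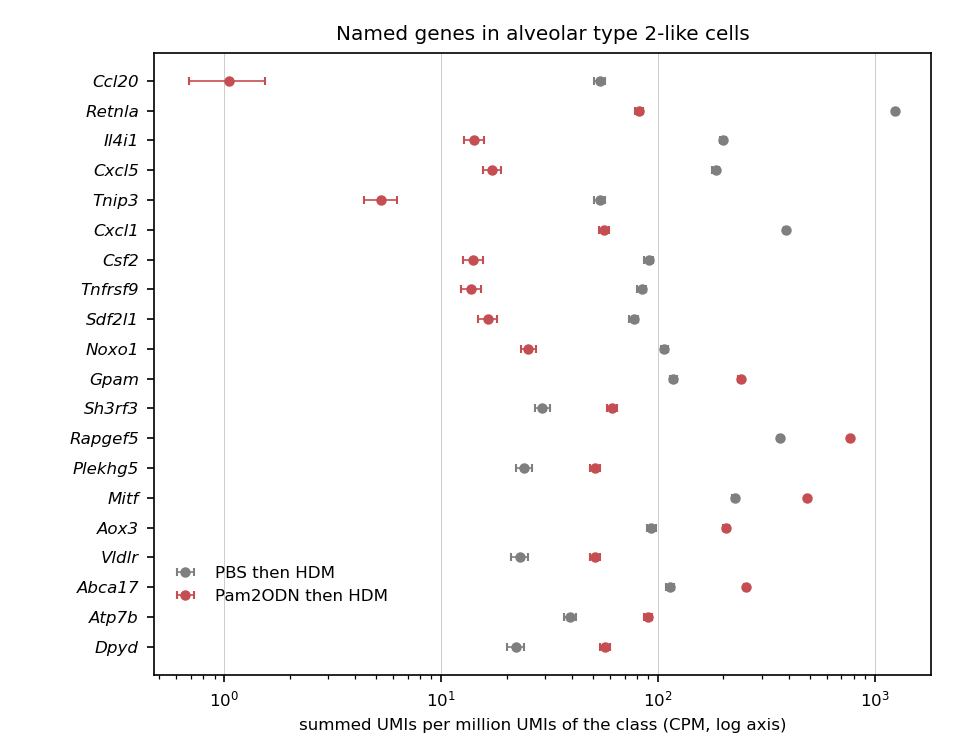
Summed UMIs scaled to the class total (CPM, log axis) in AT2-like cells of the PBS (grey) and Pam2ODN (red) library for the 10 genes with the largest difference in each direction, 1 library per group; error bars are exact 95% Poisson intervals of counting error. Ccl20 lies at 53.8 and 1.05 CPM, and the 10 genes higher after Pam2ODN differ by 1.03 to 1.35 log2 units.

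The gene lists reported here went the same way in AT2-like cells. They are a selection from the lists fixed beforehand. The other lists, such as those of surfactant and lipid synthesis, are not reported for this class. Whether the lower levels were specific to the reported lists is therefore not shown. Of the list of NF-kB and Toll-like receptor response genes, 26 members were measured and all 26 were lower in the Pam2ODN library, 19 of them at least 2-fold, with a median log2 ratio of -1.21 (-1.42 to -1.14). Sod2, a mitochondrial antioxidant enzyme (453 and 136 CPM, -1.73), was among them. Of 11 epithelial alarm cytokines and recruiting chemokines 10 were lower (median -1.03, -1.30 to -0.75, but -0.60 in cells carrying Y-linked RNA alone and -1.51 in cells carrying Xist alone), among them Areg, a growth factor of repair (-1.21). All 24 measured members of the type I interferon response were lower (-1.04, -1.15 to -0.74), such as Zbp1, a nucleic acid sensor (-2.55). All 17 genes of MHC class I presentation were lower (-1.02, -1.06 to -0.95), such as H2-K1 (846 and 409 CPM, -1.05), Psmb8 (-1.35) and Psme2 (-1.60). Of 23 interferon gamma response genes 21 were lower (-1.02), and of 13 genes of MHC class II presentation 11 were lower (-0.49), among them H2-Ab1 (956 and 592 CPM, -0.69).

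Host defence products were lower as well. Of 23 antimicrobial and acute phase genes, 19 were lower (median -0.75, -0.81 to -0.67). Complement C3 stood at 1199 and 352 CPM (-1.77), lipocalin gene Lcn2, which starves bacteria of iron, at 7388 and 2258 CPM (-1.71), and haptoglobin gene Hp at 1573 and 543 CPM (-1.54). Of 20 genes of the transitional and injury state, 16 were lower (-0.63). Of 27 genes of oxidant production and defence, 20 were lower (-0.43), among them the NADPH oxidase subunit gene Cyba (-1.51). Cell cycle genes were few in these cells, with 25 of 26 lower (-1.73, but -0.86 in the Y-only cells), such as Mcm3 at 11.8 and 1.86 CPM. Each of these medians lay at or below percentile 0.05 of 10000 random lists matched on expression, which describes these libraries and is not a test.

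Some of this moved together with RNA of other cells and with signs of handling. Genes of the B cell activation list, which holds immediate early genes such as Egr1 beside genes of immune cells, were also lower (18 of 21, -1.58). With members kept only where AT2-like cells have at least 10% of the CPM of the class with the most, the median of the interferon gamma list was -0.58, of the type I interferon list -0.63, of the B cell list -0.56, of the NF-kB list -1.31 and of the MHC class I list -1.01. Dissociation and stress genes were lower in 18 of 22 (-0.46). Cluster 5 held 705 of the 1060 PBS cells, and cluster 2 held 1078 of the 1310 Pam2ODN cells. Cluster 5 was led by Lcn2, Retnla and Cxcl5, which are among the lower genes above. The haemoglobin gene Hbb-bs, a gene of red blood cells, was also among its top 10 genes.

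Fewer AT2-like cells carried these transcripts. After thinning to 1000 UMIs, which left out 3 and 8 cells, a UMI of Csf2 was found in 7.1% (5.62 to 8.81) of the PBS cells and 1.08% (0.589 to 1.8) of the Pam2ODN cells, and of Cxcl1 in 20.6% (18.2 to 23.2) and 4.3% (3.27 to 5.55). Ccl20 was found in 1.8% and in 0 of 1302 cells, where the interval reaches 0.283% of cells with a UMI at this thinned depth. Il33, an epithelial alarm cytokine, was found in 28.9% (26.2 to 31.8) and 22% (19.7 to 24.3). Unthinned, Csf2 was in 41.1% and 17.9%, Cxcl1 in 62.4% and 23.7%, Ccl20 in 11.1% and 0.458%, and Il33 in 83.7% and 81.1%. B-cell-like cells, which should lack these genes, had thinned shares of 0.084% and 0% for Csf2, 1.18% and 0.654% for Cxcl1, 0.168% and 0% for Ccl20, and 0.756% and 0.871% for Il33. Median depths were 19764 and 18497 UMIs in AT2-like cells and 6539 and 6055 in B-cell-like cells. Tslp, another alarm cytokine, was in 0.0946% and 0% of thinned AT2-like cells, and Il25 in none.

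Among these genes, Ccl20 (ENSMUSG00000026166) lies on chromosome 1 from 83116766 to 83119167 of the mm10 build. Csf2 (ENSMUSG00000018916) is on chromosome 11 from 54247271 to 54249667, and Retnla (ENSMUSG00000061100) on chromosome 16 from 48842551 to 48844461. All 3 are annotated as protein-coding, and the UMIs were counted over each gene as a whole.

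AT1-like cells of the Pam2ODN library had lower levels of interferon-induced genes. Of 20 measured type I interferon response genes, 18 were lower, 15 of them at least 2-fold, with a median log2 ratio of -1.43 (-1.74 to -1.19). Ifit3, an antiviral gene, stood at 165 and 25.8 CPM (-2.68, -3.29 to -2.11, with 34.6% of its PBS UMIs in 1 cell), Ifit1 at -2.01 and Xaf1 at -1.48. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818) had the lowest ratio (269 and 10.5 CPM, -4.68), but 1 cell held 69.3% of its PBS UMIs, and 1 cell held 65.4% of those of Ifit2 (-2.42). With each cell counted alike, the list's median was -0.79. Further lower genes were Tubb2a (-2.33), Ankrd1, a stretch-response gene (420 and 86.9 CPM, -2.27), F3, the tissue factor that starts clotting (327 and 74.9 CPM, -2.13), Lrp1b (-2.02), Klf12 (-1.96) and Ppa1 (-1.79).

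The genes higher in AT1-like cells of the Pam2ODN library went together with AT2 transcripts. Of 24 AT2 identity and surfactant genes, 20 were higher (median 1.27, 1.09 to 1.40), among them Napsa (78.7 and 695 CPM, 3.14) and Sftpc (3060 and 17250 CPM, 2.49). With each cell counted alike this median was 0.27. The 10 genes with the largest higher values were Chia1 (5.12, from 2 PBS UMIs, with 82.7% of the Pam2ODN UMIs in 1 cell), the tight junction gene Cldn3 (35.5 and 549 CPM, 3.95, 3.41 to 4.55), Krtap17-1 (3.78), Pde7b (3.71), Sfta2 (3.65), Nkd1 (3.60), Enpep (3.58), Antxr1 (3.58), Nexmif (3.51) and Dclk1 (3.43). For Cldn3, 1 cell held 50% of the 28 PBS UMIs. Krtap17-1 had 5 PBS UMIs, and 1 cell held 54.6% of its Pam2ODN UMIs. These sums rest on 787903 and 1242142 UMIs from 266 and 228 cells.

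Mesenchymal-like cells of the Pam2ODN library had lower levels of chemokine and interferon response genes. Ccl2, the main monocyte chemokine (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), stood at 333 and 31.2 CPM (-3.41, -3.59 to -3.24). The metallothionein gene Mt2 stood at 424 and 45.8 CPM (-3.21, -3.36 to -3.07). All 26 measured NF-kB response genes were lower (median -1.23, -1.31 to -1.11), among them Sod2 (-1.75), Socs3 (-1.43) and Cxcl1 (-1.41). All 23 measured type I interferon response genes were lower (-0.91, -1.16 to -0.80), among them Ifit1 (-3.31) and Isg15 (-2.85, with 32.1% of its PBS UMIs in 1 cell). This median was -0.34 in cells carrying Xist alone and -1.95 in cells carrying Y-linked RNA alone. Rsad2 (-7.24) and Cxcl10 (-4.58) had the lowest and the next ratio, but 1 PBS cell held 70.5% and 66.4% of their UMIs. Cxcl10 was 0.22 in Xist-only cells.

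Higher in mesenchymal-like cells of the Pam2ODN library were Nrep (57.8 and 144 CPM, 1.32), Snai2, a fibroblast transcription factor (1.27), Fhit (1.26), Scube2 (164 and 381 CPM, 1.22) and Zbtb16 (1.13). After thinning to 1000 UMIs, Ccl2 was found in 10.1% and 1.53% of mesenchymal-like cells (18.9% and 4.41% unthinned). The alarm cytokine gene Tslp was found in 2.81% (1.67 to 4.4) and 4.6% (3.45 to 6.01), and in 14.6% and 22.5% unthinned. Thinning left out 146 and 163 cells, and the median depths were 4116 and 6722 UMIs. The B-cell-like thinned shares were 0.672% and 0.218% for Ccl2 and 0% in both libraries for Tslp. Cluster 6 held the most PBS cells of this class (321 of 787) and cluster 9 the most Pam2ODN cells (476 of 1271).

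Endothelial-like cells of the Pam2ODN library had lower levels of inflammatory genes. Bcl3, an NF-kB regulator (-1.41), and Gadd45g, a stress gene (-1.29), were lower. Of 25 NF-kB response genes 24 were lower (median -0.97, -1.02 to -0.89), with Cxcl1 at -2.27 and Cxcl2 at -1.95. The median was -0.65 with members of low relative level left out. Kcnq5 (-3.02), a leading gene of a mesenchymal-like cluster, and Fabp4 (-1.32) had 37.6% and 41.1% of their PBS UMIs in 1 cell. Higher were the lymphatic growth factor gene Vegfc (36.6 and 87.7 CPM, 1.26, 1.04 to 1.49), Tll1 (1.15), Gask1b (1.13), Glp1r (0.97) and Dnm3 (0.97). Vegfc and Dnm3 lead endothelial-like cluster 26, which had 20 and 95 cells. Cluster 4 held the most PBS cells (497 of 1126) and cluster 3 the most Pam2ODN cells (897 of 1751), and the median depths were 2245 and 6088 UMIs.

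Alveolar-macrophage-like cells of the Pam2ODN library had lower levels of inflammatory cytokine genes. Tnf, the early inflammatory cytokine (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), stood at 548 and 114 CPM (-2.27, -2.37 to -2.16). Of 22 measured proinflammatory macrophage genes 17 were lower (median -0.85, -0.90 to -0.74), among them the neutrophil chemokines Cxcl1 (-1.27) and Cxcl3 (-1.09) and the interleukin gene Il1a (710 and 312 CPM, -1.19). This median was -0.32 in cells carrying Y-linked RNA alone. The cytokine feedback gene Cish (-1.94), Dcstamp, of cell fusion (-1.86), and Spata7 (-1.73) were lower as well. Higher were Lepr, the leptin receptor gene (1.79), the interleukin 6 receptor gene Il6ra (40.3 and 139 CPM, 1.78, 1.55 to 2.02), Fn1 (229 and 672 CPM, 1.55), the growth-restraining gene Txnip (186 and 536 CPM, 1.52) and Adam22 (1.52). Fn1 is also a marker used here for classical monocytes.

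All 23 measured cell cycle genes were lower in alveolar-macrophage-like cells (-1.64, -2.23 to -1.41), on few UMIs. The median was -0.53 over members of at least 100 UMIs. Tnf was found in 21.2% and 6.03% of these cells after thinning to 1000 UMIs, which left out 41 and 51 cells, and in 51.1% and 25.9% unthinned. B-cell-like cells had thinned shares of 0.84% and 0.218%, at median depths of 6539 and 6055 UMIs against 18910 and 18132. In classical-monocyte-like cells, 8 of 9 measured alarm and recruiting genes were lower (-2.14, -2.51 to -1.88). These included Ccl7 (151 and 9.56 CPM, -3.99), Ccl2 (707 and 139 CPM, -2.35) and the eosinophil chemokine gene Ccl24 (338 and 88.4 CPM, -1.94). Il1a was also lower there (-2.60), but stood at 0.03 in cells of at least 500 genes and at most 5% mitochondrial UMIs.

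Neutrophil-like cells of the Pam2ODN library had lower levels of some activation genes and higher levels of Tsc22d3 and Zfp36l2, which restrain inflammatory transcripts. Of 29 activation and recruitment genes 19 were lower (median -0.39, -0.42 to -0.35), 3 of them at least 2-fold. These were Cxcl3 (1239 and 317 CPM, -1.96, -2.08 to -1.85), Sod2 (-1.64) and Il1a (1030 and 457 CPM, -1.17), and Icam1 stood at -0.97. The list shares members with the markers that define the class, and activation genes lead cluster 12, which held 267 of the 644 PBS cells and 118 of the 477 Pam2ODN cells. Tsc22d3, the glucocorticoid-induced gene GILZ (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), had the largest higher value (126 and 404 CPM, 1.68, 1.52 to 1.84). Other higher genes were Myo5a (1.42), Elmsan1 (1.31), Zfp36l2, an RNA-destabilizing protein (424 and 1016 CPM, 1.26), St3gal5 (1.22), Srpk2 (1.20), the immediate early gene Fos (1443 and 3228 CPM, 1.16), Ubash3b (1.12) and Gpr65 (1.11).

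Of the 10 lowest ratios in neutrophil-like cells, 8 belonged to genes with their highest CPM in AT2-like cells. All 24 AT2 identity and surfactant genes were lower (-1.53, -1.75 to -1.36), with Sftpd at -3.10 and Sftpc at 9095 and 2148 CPM (-2.08). With the 8% of barcodes with the highest doublet scores left out, that median was 0.22. The lower genes Cpm (-2.61), Cxcl15 (-2.54), Ank3 (-2.45), Itga9 (-2.44), Ptprf (-2.30), Gclc (-2.04), Hc (-1.99) and Ctsc (-1.97) were at 10.1% to 13% of the CPM of the class with the most, and Ank3 and Itga9 stood at 0.66 and 0.87 in cells of at least 500 genes and at most 5% mitochondrial UMIs. Camp, a granule gene of immature neutrophils, had 286 and 0 UMIs, and Ngp stood at -4.60, but at 0.70 in Xist-only cells. For both, 1 cell held most of the PBS UMIs (60.8% and 64.7%).

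T-cell-like cells of the Pam2ODN library had lower levels of immediate early, heat shock and interferon genes and higher levels of some proliferation genes. Jun stood at 410 and 115 CPM (-1.83, -1.95 to -1.71), the cytokine inhibitor gene Socs3 at -1.72 and the heat shock gene Hspa1b at 422 and 139 CPM (-1.60). Hspa1a (-1.43), Ppp1r15a (-1.17), Taf13 (-1.10), Bcl6 (-1.04), Junb (-0.92), Dnajb9 (-0.92) and Il21r (-0.87) were the other lower genes. Of 22 dissociation and stress genes 21 were lower (median -0.87, -0.92 to -0.75). These genes are also induced by tissue digestion. Different sub-clusters held the T-cell-like cells of each library: T1 held 326 and 92 cells, T2 63 and 193, and T3, led by Hspa1a, 208 and 44. The interferon genes Ifit1 and Isg15 led T11 (19 and 3 cells). Of 24 type I interferon response genes 23 were lower (-0.83, -1.03 to -0.59).

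Cell cycle genes were higher in T-cell-like cells of the Pam2ODN library in 24 of 29 (median 0.43, 0.36 to 0.73, and 0.75 in Xist-only and 0.98 in Y-only cells). Top2a stood at 19.9 and 52.1 CPM (1.39, 1.13 to 1.65) and Mki67 at 15.9 and 32.5 CPM (1.03), with UMIs of Top2a in 63 and 48 cells. Both lead sub-cluster T12, which held 7 and 12 cells. The histone genes Hist1h1b (0.90), Hist1h2ae (0.86) and Hist1h2ap (0.85) were higher too. Their UMIs lay in 29 and 17, 102 and 51, and 196 and 80 of the 1087 and 670 cells, in that order. For Hist1h1b, 1 cell held 38.1% and 30.6% of them. Top2a, Mki67 and these 3 histone genes turned to -0.11, -0.44, -0.94, -0.72 and -0.41, in that order, in cells of at least 500 genes and at most 5% mitochondrial UMIs. Further higher genes were St6galnac3 (1.09), Adam19 (0.90), the integrin gene Itgb1 (0.87), Trerf1 (0.86), S100a4 (185 and 331 CPM, 0.83) and Maf, a cytokine regulator (0.71). Itgb1, S100a4 and Maf lead the regulatory-like sub-cluster T5, which held 79 of 1087 PBS cells and 92 of 670 Pam2ODN cells. Of 11 measured type 2 effector genes 6 were higher (0.36, -0.09 to 0.67), a median that was -0.27 in cells carrying Y-linked RNA alone. Areg stood at 0.99 (0.42 to 1.55) on 52 and 59 UMIs, but these lay in 31 and 12 cells, 1 cell held 39% of the Pam2ODN UMIs, and the ratio was -1.98 in the Y-only cells.

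B-cell-like cells of the Pam2ODN library also had lower levels of immediate early and heat shock genes. Fosb stood at 99.1 and 25.6 CPM (-1.95, -2.20 to -1.71), Hspa1b at 292 and 97.5 CPM (-1.58) and Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222) at 441 and 182 CPM (-1.28). Hspa1a (-1.54), Nr4a1, a gene of antigen receptor signalling (-1.25), Fos (-1.14), the cyclin gene Ccnd2 (-1.09), the growth gene Myc (-1.09), Ppp1r15a (-1.08) and the interferon-induced gene Ifi27l2a (547 and 266 CPM, -1.04) were the others. All 22 dissociation and stress genes were lower (-1.08, -1.20 to -0.90), and 21 of 23 type I interferon response genes (-1.11, -1.33 to -0.88, and -0.58 with members of low relative level left out). Cell cycle genes were higher in 21 of 29 (0.45, 0.24 to 0.76), a direction that other settings turned. Higher genes were Sh2d3c (1.01), Sesn1, a stress-induced brake on growth (134 and 250 CPM, 0.90), Taco1 (0.82), Zfp36l2 (0.80), Rgl1 (0.68), Slc14a1 (0.62), Zfp318, which B cells need to make IgD (0.57), Ptpn22 (0.56), Ppp1r21 (0.56) and Fry (0.55).

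**Figure D3:**
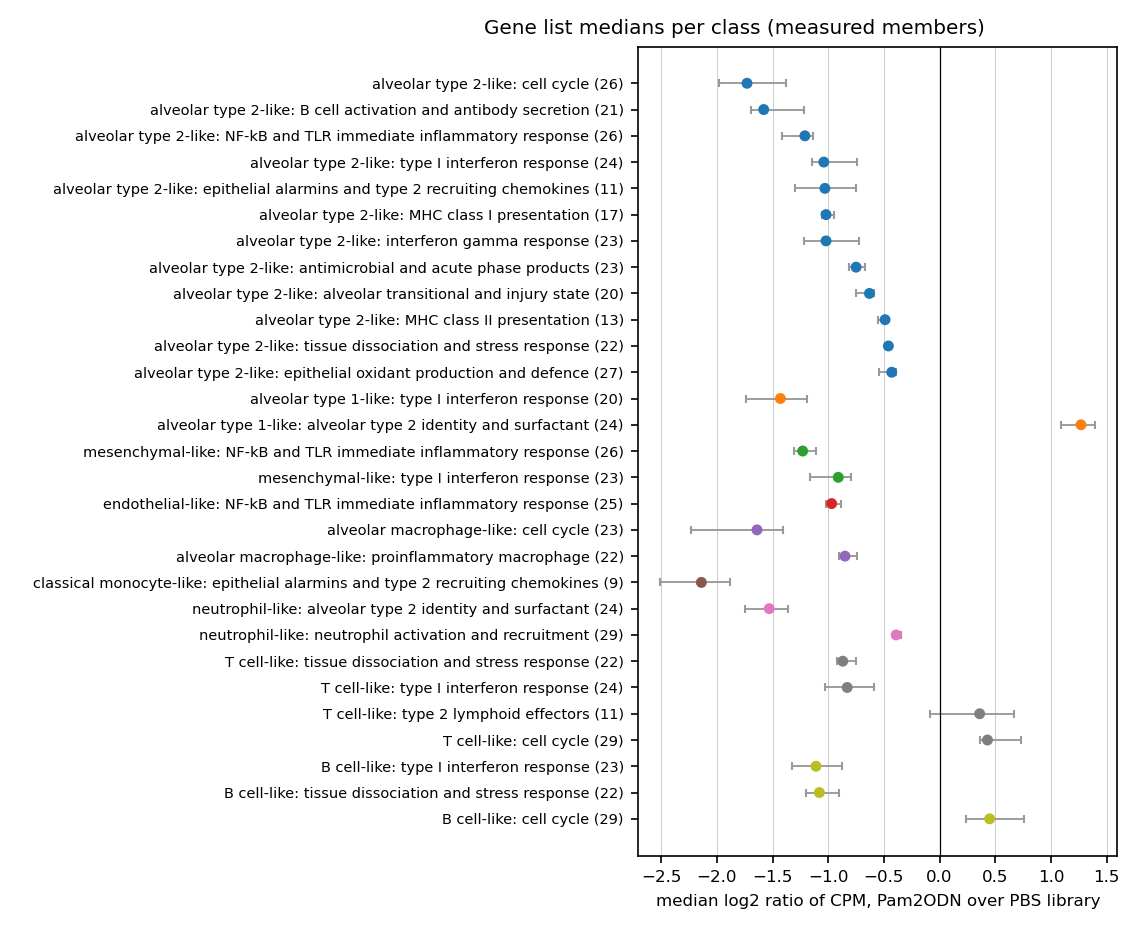
Median over the measured members (number in parentheses) of the log2 ratio of CPM, Pam2ODN over PBS library, for the gene lists named per class, coloured by class; points are medians of 1 library per group and bars 95% intervals from 400 Poisson draws of the counts. Of the medians shown, all but 4 lie below 0, from -0.39 to -2.14, and the AT2 identity list in AT1-like cells stands at 1.27. The lists shown are a selection, so this count does not cover the lists left out.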

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

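The tests of free RNA at 1 level per droplet and at the level that markers show, both tests with marker genes left out of the clustering and the tests of the mix of sexes for each share apart were chosen only after the result was seen. Further conditions, not among the limits set beforehand, leave open both accounts of the low-UMI barcodes and the mix of sexes for both shares together.

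In AT2-like cells all 26 measured NF-kB response genes were lower in the Pam2ODN library (median log2 ratio -1.21), and free RNA, tissue handling and a different mix of male and female mice were set against the pretreatment with Pam2ODN, which stays open and untested, since with 1 library per arm it cannot be told apart from any other difference between the libraries. For free RNA, the test chosen beforehand met the limit set for free RNA. The PBS excess in CPM was at a median only 0.829 times the level in B-cell-like cells. This ratio had quartiles of 0.356 and 5.87 and was over 3 in 9 of 26 genes. It cannot decide, because the classes differ in median depth (6539 UMIs in B-cell-like and 19764 in AT2-like PBS cells). Free RNA at 1 level per droplet makes up more of the CPM in the shallower cells. Counted in UMIs per cell, the same comparison gave 2.74 (1 of the 12 comparators tried later). Whether B-cell-like cells express these genes themselves was not tested. Another 12 comparators were tried after the result was seen, and their medians ran from 0.284 to 6.66, with 6 of all 13 above 3, so the outcome depends on the comparator and free RNA stays open for the list as a whole. The highest was the PBS excess in UMIs per AT2-like cell over the UMIs per cell of the class with fewest. It rested on shallow AT1-like cells (median 841.5 UMIs) in 16 of 26 genes and was 2.93 without the 3 shallowest classes. The excess over the free RNA that markers of the other classes show was at a median 3.82 times. This ratio was over 3 in 15 of 26 genes, the most in Ccl20 (383) and Cxcl5 (301). In 5 genes (Map3k8, Il1b, Il1a, Irak3 and Tnf) the excess was at or below that free RNA. The 12 members past the free RNA guard were all lower (-1.31). With PBS cells weighted to the stress gene levels of the Pam2ODN cells, the stress median went from -0.45 to 0.03 while the NF-kB median stood at -1.04, which argues against handling as the whole cause, as medians of -1.55 in Xist-only and -1.11 in Y-only cells do against the mix of sexes.

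Among immune cells the Pam2ODN library held more alveolar-macrophage-like and fewer classical-monocyte-like cells. With all marker genes left out of the clustering, the alveolar-macrophage-like fold was 3.41, which argues against clustering on markers that differ for that part. The clusters were still named by these markers, so an effect of the naming was not tested. The classical-monocyte-like fold was 0.952, so the monocyte part may come from the clustering. For a mix of sexes, the test chosen beforehand gave a ratio of both folds of 3.38 in Xist-only and 10.8 in Y-only cells. Both values passed the limit set beforehand against the mix. In Xist-only cells, however, the alveolar-macrophage-like fold alone carries the ratio, so it decides nothing for both shares together. Taken apart, the alveolar-macrophage-like fold was 3.52 and 4.59, which argues against the mix for that part, while the classical-monocyte-like fold was 1.04 and 0.424 and Xist-only cells were 28.1% and 57% of the singly marked monocytes, which leaves it open there. The sort, the digestion and the number of animals cannot be told apart from the pretreatment, with 1 library per arm.

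Low-UMI barcodes led by Scgb1a1, in no named class, were 7.03% of the cells kept in the PBS library and 2.07% in the Pam2ODN library, a signal in barcodes that no comparison uses. The ratio of Scgb1a1 to Sftpc UMIs was 6.10 log2 units above that in B-cell-like cells of the PBS library (Scgb1a1 at 121423 against 82.5 CPM). This passed the limit set beforehand against empty droplets with free RNA. Scgb1a1 is, however, the gene that drew these barcodes together, so such droplets stay open. The other secretory markers summed to 5479 CPM, which is 69.2 times the level in B-cell-like cells (79.2) and below that in secretory-like cells (17974). This met the limits set beforehand for damaged secretory cells, but these markers lead the cluster too. Genes of other cells were high as well (haemoglobin gene Hbb-bs at 679 against 1.23 CPM, Sftpc at 33542 against 1567) and Scgb1a1 stood above its level in secretory-like cells (28321 CPM), so damaged secretory cells stay open. Whether the pretreatment or the handling of the tissue set their number was not tested.

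Barcodes above the mitochondrial limit, which no comparison uses, numbered 1932 in the PBS library and 2233 in the Pam2ODN library. Cells with Y-linked and no Xist UMIs stood beside Xist-only cells in both libraries, a signal outside the comparisons: 33.4% and 29.4% of cells had Y-linked UMIs alone, against 29.4% and 38.7% with Xist alone and 5.71% and 4.86% with both.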

How the results depend on the processing

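Xist-only cells, Y-only cells, cells of at least 1000 UMIs, the top cell left out, totals without Gm42418 and AY036118, marker genes left out of the clustering, and the top 8% of Scrublet scores for list medians were alternatives chosen after seeing the data. No paired analysis was possible because each group has 1 library and no test was run.

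Over all alternatives, 154 of 184 share folds stayed within counting error of the reported value, 24 moved and 6 reversed, counting a turn as a reversal only where the interval of the reported value excludes equality. Of list medians, 240 of 319 stayed, 74 moved and 5 reversed, and of 167 single genes, 1288 of 1667 values stayed, 367 moved and 12 reversed. Of the genes that reversed, 9 did so under the stricter cell filter, 2 in Xist-only and 1 in Y-only cells. Over its alternatives the alveolar-macrophage-like fold ran from 3.12 to 4.59, the T-cell-like fold from 0.696 to 0.776 and the NK-cell-like fold from 0.598 to 0.68. The AT2-like medians ran from -1.55 to -1.11 for the NF-kB list and from -1.07 to -0.63 for the type I interferon list. For every value that follows, the cause was not tested.

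In cells of at least 500 genes and at most 5% mitochondrial UMIs the AT1-like fold reversed to 1.96, and folds were 3.72 for alveolar-macrophage-like, 0.768 for classical-monocyte-like, 1 for neutrophil-like, 1.22 for AT2-like and 0.548 for regulatory-T-like cells. Genes that reversed there were Top2a (-0.11), Mki67 (-0.44), Hist1h1b (-0.94), Hist1h2ae (-0.72) and Hist1h2ap (-0.41) in T-cell-like cells, Ank3 (0.66), Itga9 (0.87) and Sftpc (0.35) in neutrophil-like cells, and Il1a (0.03) in classical-monocyte-like cells. The alveolar-macrophage-like and classical-monocyte-like folds were 3.94 and 0.746 at resolution 0.5, 3.63 and 0.837 with response genes left out, and 3.78 and 0.765 with cells thinned to 2000 UMIs, where the dendritic-like fold reversed to 0.761. With marker genes left out of the clustering, folds were 0.952 for classical-monocyte-like, 1.06 for interstitial-macrophage-like and 0.823 for regulatory-T-like cells. In cells of at least 1000 UMIs, folds were 0.97 for AT1-like and 1.01 for AT2-like cells, and the AT2 identity median of AT1-like cells was 1.97.

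With the top 8% of Scrublet scores left out, the dendritic-like fold was 2.75, and the cell cycle median of B-cell-like cells (-0.86) and the AT2 identity median of neutrophil-like cells (0.22) reversed. Other medians were -0.63 for proinflammatory genes in alveolar-macrophage-like cells, -0.73 for NF-kB genes in endothelial-like cells, -0.52 for activation genes in neutrophil-like cells, 1.07 for AT2 identity in AT1-like cells, and -0.73 for B cell activation and -1.33 for the cell cycle in AT2-like cells. Over members past the free RNA guard, AT2-like medians were -0.63 for type I interferon, -0.58 for interferon gamma, -0.46 for MHC class II, -0.83 for the transitional state, -0.38 for oxidant genes, -0.56 for B cell activation and -1.12 for the cell cycle. Elsewhere they were -0.85 for stress and -0.58 for type I interferon in B-cell-like cells, -0.58 for type I interferon in T-cell-like cells, -1.34 for the cell cycle in alveolar-macrophage-like cells, -0.65 and -0.99 for NF-kB in endothelial-like and mesenchymal-like cells, and 1.41 for AT2 identity in AT1-like cells. Over members of at least 100 UMIs, cell cycle medians were -0.53 in alveolar-macrophage-like, 0.22 in B-cell-like and -1.32 in AT2-like cells, and type I interferon -0.73 in B-cell-like cells. With every member of 1 UMI the mesenchymal-like NF-kB median was -1.32. With each cell counted alike, the B-cell-like cell cycle median reversed to -0.03, and others were -0.79 for type I interferon and 0.27 for AT2 identity in AT1-like cells, -0.94 for MHC class I and -0.39 for oxidant genes in AT2-like cells, -1.44 for NF-kB in mesenchymal-like cells, -0.49 for activation and -0.48 for AT2 identity in neutrophil-like cells, 0.80 for type 2 effectors in T-cell-like cells, and -1.82 for alarm genes in classical-monocyte-like cells.

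In Xist-only cells the classical-monocyte-like and AT1-like folds both reversed to 1.04, and folds were 1.61 for interstitial-macrophage-like, 1.02 for AT2-like, 0.858 for B-cell-like and 1.97 for nonclassical-monocyte-like cells. AT2-like medians were -1.13 for MHC class I, -1.55 for NF-kB, -1.51 for alarm genes, -0.63 for MHC class II, -0.54 for stress, -1.24 for interferon gamma, -0.78 for the transitional state, -0.32 for oxidant genes and -2.06 for the cell cycle. Others were -0.58 for stress and 0.75 for the cell cycle in T-cell-like cells, -1.14 for proinflammatory genes in alveolar-macrophage-like cells, -0.82 for NF-kB and -0.34 for type I interferon in mesenchymal-like cells, -0.29 for activation and -2.41 for AT2 identity in neutrophil-like cells, 1.42 for AT2 identity in AT1-like cells, and -1.46 for alarm genes in classical-monocyte-like cells. The cell cycle median of B-cell-like cells (-0.14), Cxcl10 in mesenchymal-like cells (0.22) and Ngp in neutrophil-like cells (0.70) reversed.

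In Y-only cells the AT1-like (1.33) and AT2-like (0.979) folds reversed, and folds were 4.59 for alveolar-macrophage-like, 0.424 for classical-monocyte-like and 4.47 for interstitial-macrophage-like cells. AT2-like medians were -0.91 for MHC class I, -1.11 for NF-kB, -0.60 for alarm genes, -0.38 for MHC class II, -0.54 for stress, -0.72 for interferon gamma, -0.56 for oxidant genes, -1.0 for B cell activation and -0.86 for the cell cycle. Others were -0.98 for stress, 0.98 for the cell cycle and -0.27 for type 2 effectors in T-cell-like cells, -0.54 for the cell cycle and -0.32 for proinflammatory genes in alveolar-macrophage-like cells, -1.75 for type I interferon and 2.26 for AT2 identity in AT1-like cells, -0.77 for NF-kB in endothelial-like cells, -1.47 for NF-kB and -1.95 for type I interferon in mesenchymal-like cells, and -0.43 for activation and -1.85 for AT2 identity in neutrophil-like cells. The cell cycle median of B-cell-like cells (-0.45) and Areg in T-cell-like cells (-1.98) reversed.

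With at least 10 UMIs and no minimum on CPM, both changed together, 13 of the 130 genes were named again, since genes of few UMIs with larger ratios then come first: 5 of 20 in AT2-like, 4 of 20 in AT1-like, 2 of 20 in neutrophil-like, 2 of 10 in mesenchymal-like and 0 in B-cell-like, T-cell-like, alveolar-macrophage-like and endothelial-like cells. With no free RNA guard 94 of 130 were named again, among them 5 of 10 in alveolar-macrophage-like, 6 of 10 in endothelial-like and 12 of 20 in neutrophil-like cells. All 16 shares of cells with a UMI that were recomputed kept their direction when thinned to 500 UMIs and unthinned.

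Some alternatives gave no value, since the clusters no longer gave the class a name. This was so for interstitial-macrophage-like cells with the top 8% left out, for dendritic-like cells with no filter or at resolution 0.5, for nonclassical-monocyte-like cells at resolution 0.5, thinned, or without marker genes, and for ILC2-like and gamma-delta-T-like cells without marker genes. Depth limits what can be read from cytokine genes and small classes.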

Other observations

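The genes read here were chosen after their values were seen, and no test of a hypothesis is added. Ccl2, the main monocyte chemokine gene, was found in fewer interstitial-macrophage-like and classical-monocyte-like cells of the Pam2ODN library. Thinned to 1000 UMIs, Ccl2 was found in 51% (36.3 to 65.6) of interstitial-macrophage-like cells of the PBS library and 12.6% (6.89 to 20.6) of the Pam2ODN library, and in 74.5% and 29.2% unthinned. Thinning left out 2 and 3 of 51 and 106 cells, and their median depths were 16857 and 10420 UMIs. In classical-monocyte-like cells Ccl2 was found in 16.2% and 4.12% after thinning (43.6% and 16.5% unthinned) and the eosinophil chemokine gene Ccl24 in 14.5% and 7.06% (45.5% and 29.4% unthinned), with none left out. B-cell-like cells had thinned shares of 0.672% and 0.218% for Ccl2 and of 0.084% and 0.109% for Ccl24, at median depths of 6539 and 6055 UMIs against 16772 and 14650 in classical-monocyte-like cells. These classes depend on the clustering, so the cells compared can differ in kind.

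In AT2-like cells, Retnla was found after thinning in 28.2% (25.5 to 31) of the PBS cells and 3.53% (2.6 to 4.68) of the Pam2ODN cells (55.4% and 17% unthinned), Cxcl5 in 7.76% and 0.922% (27.5% and 5.42%), and Areg in 12.1% and 6.45% (47.3% and 26.7%). The B-cell-like shares were 1.26% and 0.218% for Retnla, 0.336% and 0.109% for Cxcl5, and 0.252% and 0.218% for Areg. Il17a, the cytokine gene of gamma-delta and helper T cells that calls in neutrophils, was found after thinning in 0 of 1085 T-cell-like cells of the PBS library, which allows up to 0.339% of cells with a UMI at that thinned depth and sets no limit on expression, and in 0.746% (0.243 to 1.73) of 670 Pam2ODN cells. Unthinned it was in 0.46% and 2.24%, with thinned B-cell-like shares of 0% in both libraries. Median depths were 8849 and 8421.5 UMIs in T-cell-like cells. Il17a is among the top 10 genes of the gamma-delta-like sub-cluster T9, which held 12 and 18 cells. Its shares can therefore follow the size of that sub-cluster. Among T-cell-like subsets, CD8-like cells were 7.27% and 5.39% of immune cells (0.742-fold, 0.619 to 0.889), a share that the larger alveolar-macrophage-like share lowers too. Regulatory-like T cells, which restrain allergic responses, were 3.34% and 3.71% (1.11-fold, 0.873 to 1.42), but 0.548-fold in cells of at least 500 genes and at most 5% mitochondrial UMIs and 0.823-fold without marker genes in the clustering, so the direction was not settled. This class joined sub-clusters that did not move alike. They were T5 (79 and 92 cells), T7, with the regulatory marker Foxp3 among its top 10 genes (46 and 18), and T12, led by cell cycle genes (7 and 12). Gamma-delta-like T cells were 0.304% and 0.548% (1.8-fold, 0.87 to 3.74), a difference not detectable at this depth.

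Classes too small to compare held few cells. Plasmacytoid-dendritic-like cells numbered 29 and 26, basophil-like cells 9 and 10, ciliated-like cells 54 and 49, secretory-like cells 10 and 12, and mesothelial-like cells 8 and 22. The secretory-like count leaves out the unnamed Scgb1a1-led cluster of 568 and 171 barcodes. Nonclassical-monocyte-like cells were 2.76% and 3.53% of immune cells (1.28-fold, 0.989 to 1.66), a difference within counting error, and the fold was 1.97 in Xist-only cells. Of the clusters without a name, cluster 22, led by the cardiac muscle gene Myl7, held 109 and 80 cells with median depths of 779 and 772.5 UMIs.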
